A study of Arabidopsis thaliana with 4 samples.

How the data were processed

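Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Arabidopsis thaliana seedlings that overexpress the MYB-like transcription factor RVE5 with a MYC tag. Per the labels, the seedlings were 14 days old, were grown at 22 °C with 16 h of light and 8 h of dark, were kept at 29 °C for 12 h, and were sampled at zeitgeber time 12 h. Tissue was fixed with formaldehyde and sonicated in SDS buffer, and chromatin was precipitated with an antibody against MYC, per the labels' protocols. There were 4 samples, 3 ChIP replicates and 1 input DNA library without antibody. No label says whether the 3 replicates came from separate plants, so their spread may be technical.

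The deposited data were 1 peak list for each ChIP replicate. The column names are those that the peak caller MACS2 writes, but no header names a tool. Per the submitters' processing notes, the genome build was TAIR10 and CASAVA 1.4 was used. The aligner, the peak caller and its threshold, and the role of the input library are not given in the sources used here, and no list of the input library was used here. Each list gave the peak's position in bp and the summit. The signal in the deposited lists was the height of the read pileup at the summit. The authors' lists also gave a fold over a local background, the −log10 of a p-value and the −log10 of a q-value for each peak. These folds and p-values belong to each peak in its own list, and were used to describe, rank and filter peaks. A mean fold ± SD over the 3 lists describes how far the lists differ at the same region and is not a measure of occupancy on a common scale.

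The total number of reads of each library is unknown here. The median pileup at the summit was 38, 39 and 40 reads in replicates 1, 2 and 3. A count of that size has an exact 95% Poisson interval of 26.9 to 52.2, 27.7 to 53.3 and 28.6 to 54.5 reads, if each unit of pileup is 1 independent read or fragment. These intervals cover counting error only.

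Peaks of the 3 lists were merged into regions where they shared at least 1 bp. A region with a peak in every replicate is called shared, and the shared regions are the main set. The number of shared regions was set against 10000 random placements of each replicate's peaks on their own chromosome, with widths kept, in a one-sided test. The last peak end served as the chromosome end. Ranks of the fold were compared between replicates by Spearman's rho across regions, which are not independent replicates, so no p-value is given.

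Gene names and gene neighbours came from a table of RefSeq genes on assembly TAIR10.1, with 27432 protein-coding genes on the 5 nuclear chromosomes. Region coordinates are those of the deposited lists on TAIR10, 1-based, and no gene coordinates are printed. The positions were checked by shifting the shared regions along the chromosomes: 38.7% of their centres lay inside a protein-coding gene without a shift, against 56.8% to 66.3% under 14 shifts. The smallest shift was 1000 bp, so smaller offsets were not tried. The same 38.7% is given under Results, so the check and that result are not independent. No genome sequence was used here, so the planned searches for 14 fixed motifs, for words of 6 and 8 bases and for the evening element were not run, and no genes were named by motif. The table gave no strand. The planned classes of promoter, untranslated region, exon and intron were therefore replaced by 4 classes of the region centre: inside a protein-coding gene, inside another annotated gene, within 1000 bp beside a protein-coding gene, or farther away. Each class was compared with 10000 random placements in a two-sided test, adjusted over the classes by the Benjamini-Hochberg method.

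A gene was counted as bound when a region overlapped its span with 1000 bp added on both sides. The planned span was upstream of the transcription start only, which needs the strand. The term bound stands for this position and not for a test of occupancy. The 7 gene lists, 158 genes in all, were fixed before the data were examined, and each was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted over the 7 lists. Differences between lists were also tested by Fisher's exact test and adjusted over all pairs of lists. All 158 locus identifiers were in the gene table. For 13 of them the table did not hold the list's symbol, COR28 and RVE5 among them, and the symbol printed is that of the list.

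The genes named were chosen by a rule fixed before the data were examined. They are RVE5, the 30 list genes with the highest mean rank of the fold among the 36 bound in at least 2 replicates, and the genes of the 10 shared regions with the highest mean rank. A region's gene is the protein-coding gene whose span is nearest to its centre, in place of the nearest transcription start. Genes named outside the rule are said to have been chosen after their values were seen.

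The alternatives left out each replicate in turn, used regions of at least 2 or of any replicate, kept the better 50% of each list by p-value, and changed the overlap, the flank and the test. Alternatives chosen after the data were seen were moving regions within 100 kb of their own position, gene spans without flank, the nearest gene only, and leaving out regions with a pileup above 500. The scripts were tested on simulated data. In 5 simulations of the overlap, with 2367 peaks, all 150 planted shared regions were recovered on average. The planted peaks lay at nearly the same position in each list and had to overlap, so this checks the counting only. In 40 simulations of the list test over 27432 genes, 100% of planted lists were recovered and 0% of random lists were called. Each planted list held a fixed share of bound genes far above that of all genes. Its recovery was therefore all but certain and does not give the sensitivity for lists with fewer bound genes. Bound genes were drawn independently in these simulations, so they do not cover lists in which neighbouring genes share a region. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.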

Results

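Peaks of RVE5-MYC ChIP were mapped in warmth-treated Arabidopsis seedlings at zeitgeber time 12 h, in 3 ChIP replicates. RVE5 is a member of the REVEILLE family of MYB-like factors, relatives of the morning clock proteins CCA1 and LHY, and the series title places it in the growth of the hypocotyl at warm temperature. The question that the design allows is where in the genome the ChIP gave a peak in every replicate, and beside which genes. The design holds no second condition, so no change in binding was measured. It also holds no seedlings without the tag. Signal of the antibody that recurs without RVE5-MYC therefore cannot be told apart from its binding, also where all 3 replicates have a peak.

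The strongest region that all 3 replicates shared lay within 1000 bp of GI (AT1G22770), a clock gene that also acts in flowering, on chromosome 1 from 8060669 to 8061336. Its fold over the local background was 8.12 ± 0.250 (SD, n = 3). Further regions among the 10 with the highest mean rank lay at the clock genes PRR7, with a fold of 5.65 ± 0.937, and FKF1, with 4.67 ± 0.354. The others at genes of the fixed lists were GRP7, a clock-regulated RNA-binding protein, with 5.76 ± 0.411, COR27, with 5.28 ± 0.130, and the stress-response zinc finger gene ZAT12, with 5.85 ± 0.295 (each SD, n = 3). The remaining 4 of the 10 had BBX8 (6.43 ± 0.198) and SMT1 (4.73 ± 0.436) as their nearest genes, or lay over 2000 bp from the nearest protein-coding gene. The last kind were a region on chromosome 4 from 3056496 to 3057012, nearest to AT4G06479, with a fold of 7.87 ± 0.385, and one on chromosome 5 from 11187255 to 11187553, nearest to AT5G29560, with 5.70 ± 0.498. RVE5 itself (AT4G01280) had no peak within 3000 bp in any replicate.

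The 3 lists held 676, 827 and 864 peaks, 789 ± 99.6 (SD, n = 3), with a median fold of 2.581, 2.526 and 2.501. Merging gave 1674 regions, of which 199 (11.9%) were found in all 3 replicates, 288 (17.2%) in 2 and 1187 (70.9%) in 1. Random placement of the peaks gave 0.0207 regions in all 3 on average and 1 at most in 10000 placements, so the one-sided permutation p was 0.0001, the smallest that the placements can give. The median fold of shared regions was 3.00, against 2.56 for regions of 2 replicates and 2.405 for regions of 1. Among the 100 peaks of each list with the best p-value, 83.7 ± 4.16% (SD, n = 3) lay in a shared region, and below rank 400 the share was 8.862 ± 1.301%. Across the 199 shared regions, Spearman's rho of the fold was 0.713 between replicates 1 and 2, 0.735 between 1 and 3, and 0.738 between 2 and 3. Few peaks were strong: only 9, 8 and 11 peaks in replicates 1, 2 and 3 reached a fold of 5. Requiring summits within 100 bp lowered the number of shared regions to 121, and leaving out replicate 1 raised it to 307, since only 2 lists then had to hold a peak.

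**Figure D1:**
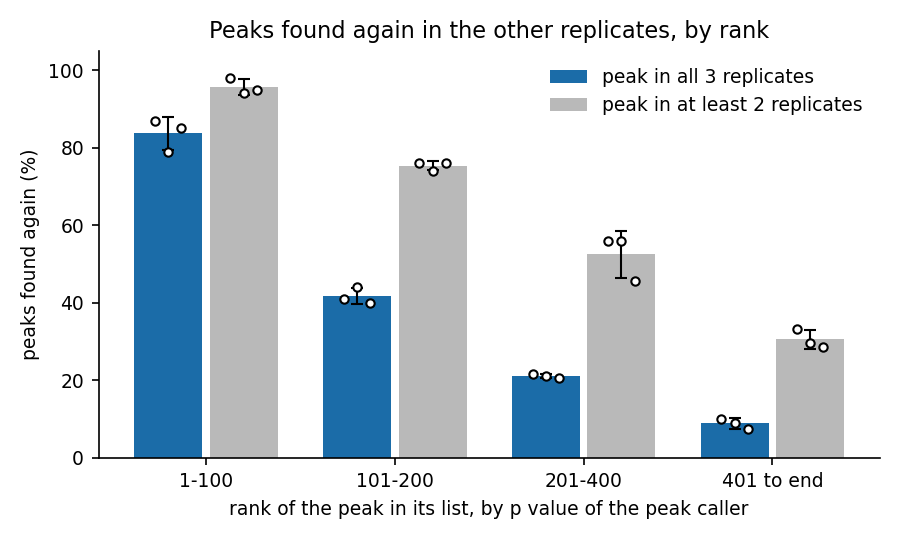
Share of the peaks of each list (vertical axis, %) that lay in a region called in all 3 replicates (blue) or in at least 2 (grey), by the rank of the peak on the p-value of the peak caller (horizontal axis). Bars are means, error bars are SDs and open circles are the 3 replicates; the blue mean falls from 83.7% for ranks 1 to 100 to 8.86% for ranks beyond 400.

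Core clock genes were bound more often than other genes. Of 28 genes in this list, 8 lay near a shared region (28.6%), against 0.960% of other protein-coding genes, with an odds ratio of 41.2 (95% confidence interval 15.6 to 98.8) and an adjusted p of 1.5e-09 in Fisher's exact test. Beside GI, PRR7 and FKF1 the bound genes were TOC1, with a fold of 4.17 ± 0.308 at chromosome 5 from 24674663 to 24675073, PRR5 (3.65 ± 0.126), ELF3 (3.38 ± 0.348), ELF4 (3.295 ± 0.725) and LUX (3.29 ± 0.417; SD, n = 3 for each). A second shared region with PRR5 as its nearest gene, on chromosome 5 from 8359689 to 8360145, lay beyond 1000 bp. Its fold was higher, 4.26 ± 0.560 (SD, n = 3). ELF3, ELF4 and LUX encode the parts of the evening complex. CCA1 and LHY, named after their values were seen, were among the 4 list genes with a peak in 1 replicate only. A further 12 of the 28 genes had no peak in any replicate. RVE7 (3.00 ± 0.267) and LNK3 (3.065 ± 0.330; both SD, n = 2) were bound in 2 replicates. So were LNK4 (2.16 ± 0.335, SD, n = 2) and, in 2 separate regions, NOX, both named after their values were seen.

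Clock output genes were also bound more often than other genes: 5 of 15 (33.3%), with an odds ratio of 51.0 (13.6 to 165) and an adjusted p of 8.79e-07. These were GRP7, COR27, COR28 (AT4G33980), with a fold of 3.95 ± 0.247, CDF1, a repressor of flowering, with 3.601 ± 0.295, and the catalase gene CAT3, with 2.91 ± 0.224 (SD, n = 3). The centre of this region of COR28 lay more than 1000 bp from the gene. A second shared region, with its centre inside COR28, had a fold of 3.515 ± 0.339 (SD, n = 3). The related gene GRP8 was bound in 2 replicates with a fold of 3.11 ± 0.0331 (SD, n = 2). The difference between the core clock and output lists did not pass its test (adjusted p = 0.820, Fisher's exact test).

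Cold response genes were bound as well. Of 11 genes, 4 lay near a shared region (36.4%, odds ratio 58.0, 12.4 to 230; adjusted p = 6.79e-06, Fisher's exact test). These were ZAT12 and the neighbouring cold regulators CBF1, CBF2 and CBF3 on chromosome 4, with folds of 3.13 ± 0.538, 3.25 ± 0.265 and 4.12 ± 0.214 (SD, n = 3). In all, 9 of the 11 genes were bound in at least 2 replicates. The other 5 were COR47 (2.94 ± 0.0234), COR15A with COR15B (1 region for both, 2.83 ± 0.307), and KIN1 with KIN2, named after their values were seen (1 region for both, 2.55 ± 0.0578; SD, n = 2 for each). CBF1, CBF2 and CBF3 are neighbours of similar sequence, so they are not independent, and how their reads were assigned is not given in the sources used here. Random placement, which keeps the genes' neighbourhood but moves each region by itself, gave 0.0816 bound genes on average on the whole chromosome (adjusted permutation p = 0.000467). Within 100 kb it gave 0.382 on average and 4 at most (adjusted permutation p = 0.00233). Of the 11 genes, 4 were bound without replicate 1, 5 without replicate 2 and 8 without replicate 3. The list of replicate 3, the longest, had peaks near 5 of the genes, against 10 and 8 for replicates 1 and 2.

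The fixed list of light and thermomorphogenesis regulators held no gene with a shared region: 0 of 23, which allows a share of up to 13.0%, and an adjusted p of 1 in Fisher's exact test. This holds for the genes of the list and not for all genes of light signalling. PIF4, a regulator of growth in warmth, was bound in 2 replicates with a fold of 3.51 ± 0.198, at chromosome 2 from 17889272 to 17889769, and the photoreceptor gene PHYB in 2 replicates with 3.02 ± 0.130 (SD, n = 2). Auxin and elongation genes gave 0 of 36 (up to 8.33%; adjusted p = 1, Fisher's exact test), and none was bound in 2 replicates. Core clock genes differed from the light list (adjusted p = 0.0249) and from the auxin list (adjusted p = 0.0130) in Fisher's exact test of the difference. The direction for light regulators depended on the regions used: without replicate 1 or without replicate 2, 1 gene was counted, with odds ratios of 2.95 and 3.19 (adjusted p = 0.347 and 0.325, Fisher's exact test). With regions of at least 2 replicates the odds ratio was 3.8 (adjusted p = 0.126), and with regions of any replicate 7 genes gave 5.33 (adjusted p = 0.00168, Fisher's exact test).

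Of 25 heat response genes 3 were counted, with an odds ratio of 13.8 (2.63 to 46.4) and an adjusted p of 0.00327 in Fisher's exact test. HSFA3, a heat shock factor, had a fold of 3.26 ± 0.587 and HSP18.2 had 2.89 ± 0.117 (SD, n = 3). HSFA1B, which was named after its values were seen, had 2.28 ± 0.214. The region at HSP18.2 has EXO70H7 as its nearest gene and that at HSFA1B has AT5G16810, so the call ends when a region counts for its nearest gene only (1 gene, adjusted p = 0.223, Fisher's exact test). It ends as well with regions of any replicate (4 genes, adjusted p = 0.137, Fisher's exact test).

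Highly transcribed leaf genes, a list fixed to look for signal that follows transcription, gave 1 of 20 (5%, odds ratio 5.29, 0.127 to 33.5; adjusted p = 0.252, Fisher's exact test). The core clock, clock output and cold lists did not pass the test of their difference from this list (adjusted p = 0.134, 0.134 and 0.125, Fisher's exact test), so a higher rate of binding than at highly transcribed genes was not shown. The bound gene was UBQ10, with a fold of 3.01 ± 0.235 (SD, n = 3). UBQ11 (3.48 ± 0.113) and RBCS1A (2.70 ± 0.297; SD, n = 2) were bound in 2 replicates. Without replicate 3 the list had 2 bound genes with an adjusted p of 0.0488, with regions of at least 2 replicates 3 with 0.0214, and with regions of any replicate 7 with 0.0008125 (all from Fisher's exact test).

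**Figure D2:**
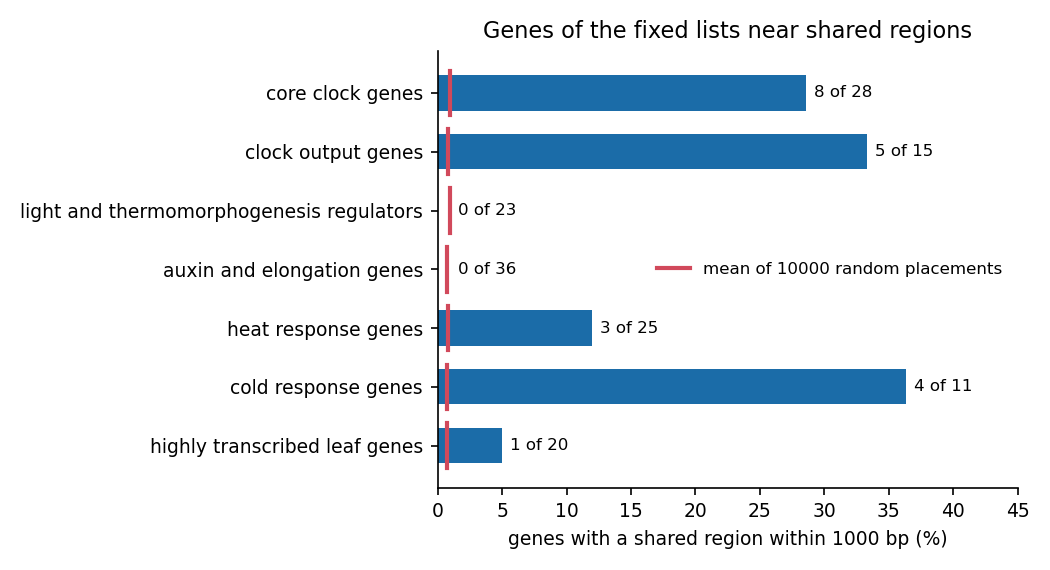
Share of the genes of each fixed list (horizontal axis, %) that had a shared region within 1000 bp of their span. Blue bars are the observed shares with their counts and red lines are means of 10000 random placements; the core clock, clock output and cold lists stand at 28.6%, 33.3% and 36.4%.

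**Figure D3:**
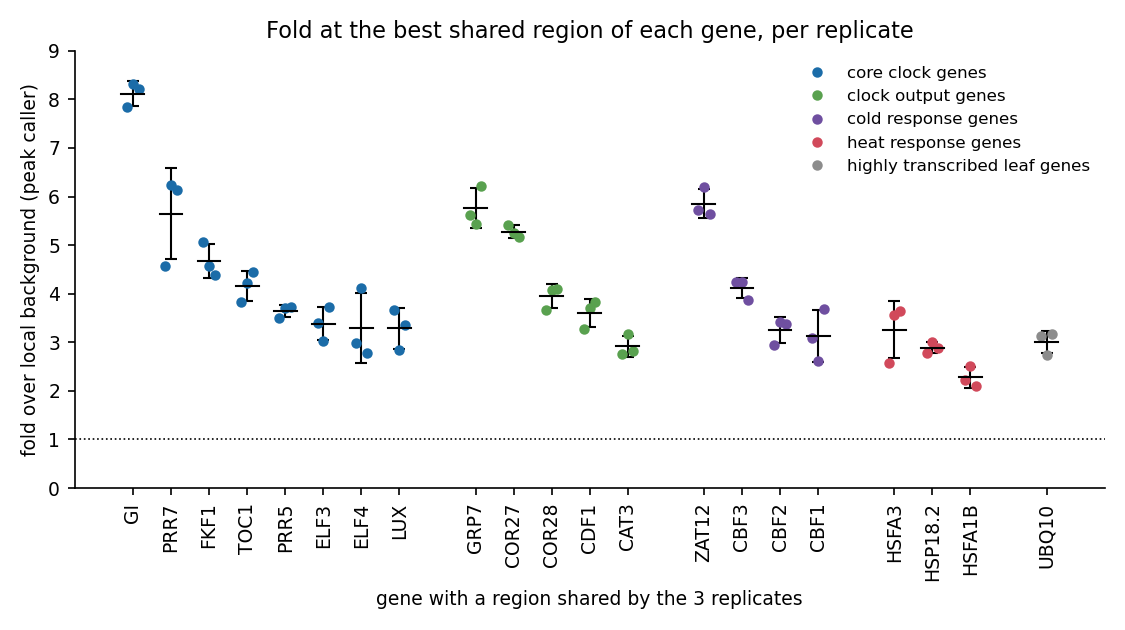
Fold over the local background as given by the peak caller (vertical axis) at the strongest shared region within 1000 bp of each list gene (horizontal axis). Points are the 3 replicates, horizontal lines are means, error bars are SDs and the dotted line marks a fold of 1; GI stands highest at 8.12.

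Against random placement, the shared regions lay beside protein-coding genes more often and inside them less often. Region centres within 1000 bp beside a protein-coding gene made up 43.2%, against 19.0% under random placement (adjusted permutation p = 0.0004), as for the regions at GI, TOC1 and PRR7. Centres inside a protein-coding gene were fewer, 38.7% against 54.0% (adjusted permutation p = 0.0004), with ELF3, CBF3 and ZAT12 among them. Within 500 bp of a gene end lay 68.3% of the centres, against 35.25% under random placement (permutation p = 0.0002, the smallest that the two-sided placements can give). Regions farther from genes were fewer as well, 9.55% against 16.8% (adjusted permutation p = 0.00693), a call that ended when regions were moved only within 100 kb (adjusted p = 0.474). Regions inside another annotated gene made up 8.54% against 10.2%, which did not pass the permutation test (adjusted p = 0.534). The share passed as a deficit with regions of at least 2 replicates (5.96%, adjusted permutation p = 0.0024), but lay above the 5.25% of placement within 100 kb (adjusted permutation p = 0.0677).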

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

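The alternatives that moved regions within 100 kb, used the nearest gene, dropped the flank or left out high pileups were chosen after the data were seen, and the others before. Of the 84 alternatives for the gene lists 75 kept direction and side of the threshold, and of 40 for the location classes 36 did. Some of the 75 could not change. The light and auxin lists had no bound gene in the main set, so alternatives that only removed regions or the flank had to give none again. Peaks with a fold of at least 5 numbered 9.33 ± 1.53 (SD, n = 3), and shared regions 121 with summits within 100 bp. Leaving out 1 replicate gave 283 to 307 shared regions, more than 199 because 2 lists then sufficed. Regions inside another annotated gene fell to 5.96% in at least 2 replicates (adjusted p = 0.0024) and to 5.56% in any (adjusted p = 0.0002, permutation tests), both past the threshold, and turned with placement within 100 kb, where 8.54% lay above a mean of 5.25% (adjusted permutation p = 0.0677). Regions farther from genes stayed at 9.55% but lost the call with placement within 100 kb, where 11.4% was the mean (adjusted permutation p = 0.474). Highly transcribed leaf genes gained the call with 3 genes in regions of at least 2 replicates, 7 in regions of any, and without replicate 3 (1 to 2 genes over the 3 left-out replicates). Light regulators, at an odds ratio of 0, turned to ratios above 1 with 1 gene without replicate 1 or 2 (0 to 1 genes over the 3 left-out replicates), 2 genes in regions of at least 2 replicates and 7 in regions of any, and passed the threshold only in the last. Heat response genes lost the call with 4 genes in regions of any replicate and with the nearest gene only (1 gene). The cause of these changes was not tested. Spearman's rho by p-value was 0.746, 0.759 and 0.769 for replicates 1 and 2, 1 and 3, and 2 and 3, and over regions in both lists of a pair 0.679, 0.708 and 0.691. Of the 35 named genes, 22 were bound by shared regions, and those 22 remained so in each alternative tested for them except spans without flank. Most of these alternatives could hardly have lost a gene. Regions of at least 2 or of any replicate and a wider flank take in the shared regions, and leaving out 1 replicate asks for fewer peaks. Keeping the better 50% of each list by p-value could lose genes, and kept all 22. Without flank 19 were kept, and GI, CDF1 and HSP18.2 were lost. Motif alternatives and the span of the promoter only were not run, for want of sequence and strand. No paired analysis was possible because only 1 group had peak lists. The pileup at a typical summit, about 39 reads, and the unknown library totals limit what can be said of regions missing from a list.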

Other observations

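All tests in this part were chosen after the results they bear on were seen. Grouping genes by the stem of their symbols and synonyms gave 197 groups of at least 10 members, called families here, of which 3 passed Fisher's exact test with adjustment. A shared stem need not be a gene family: the stems NAC and ANAC, with 82 and 100 genes, were tested apart. The gene numbers are therefore those of the stem. Of 11 PRR genes 4 lay near a shared region (adjusted p = 0.000574, Fisher's exact test): the clock genes TOC1, PRR5 and PRR7 and also APRR2, with a fold of 2.63 ± 0.416 (SD, n = 3). As 3 of these 4 also belong to the core clock list, this is not independent of that list's result. Of 12 JAZ genes, repressors of jasmonate signalling, 3 did (adjusted p = 0.0129, Fisher's exact test). These were JAZ6 on chromosome 1 from 27276585 to 27277153 (3.355 ± 0.534), JAZ9, listed as TIFY7 (3.06 ± 0.181), and JAZ1 (2.71 ± 0.225; SD, n = 3 for each).

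Of 31 BBX genes, B-box zinc finger proteins that act in light signalling and flowering, 5 lay near a shared region (16.1%, odds ratio 19.6, adjusted p = 0.00123, Fisher's exact test). They were BBX8, COL9 (4.81 ± 0.6002), BBX13 (4.48 ± 0.575), LZF1 (4.05 ± 0.182) and BBX28 (3.105 ± 0.438; SD, n = 3), and none of the BBX genes in the clock output list was among them. BBX24 of that list was bound in 2 replicates, with a fold of 2.72 ± 0.750 (SD, n = 2). One hypothesis is binding beside many members of the family. Of the 26 BBX genes left, 2 lay near a region of exactly 2 replicates (7.69%), against 1.47% of other genes (p = 0.0560, Fisher's exact test), which leaves it open. Signal at highly transcribed genes cannot be excluded either, since the shares of BBX and highly transcribed genes did not pass Fisher's exact test of their difference (16.1% against 5%, p = 0.384).

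The 1187 regions called in 1 replicate also lay beside genes: 41.5% had their centre within 1000 bp beside a protein-coding gene, against 19.0% under random placement (adjusted permutation p = 0.0002). Signal at highly transcribed genes stays open as an explanation: 5 of the 20 highly transcribed leaf genes lay near such a region, against 1.104 under placement within 100 kb (adjusted permutation p = 0.0229). At LHCB3, RBCS1B, RBCS3B and CA1, named after their values were seen, the centre of the region lay inside the gene. Those regions are not among the centres beside genes, and transcription was not measured here, so this count cannot decide the question. Weak sites of the same kind as the shared regions stay open too: of the 4 lists bound at shared regions, 1 passed under placement within 100 kb and 2 under placement on the whole chromosome. The cold list, with 4 of 11 genes, passed both (adjusted permutation p = 0.0229 and 0.00887). These genes were CBF1 and CBF2, which already had shared regions, KIN2, which had a region of 2 replicates, and ICE1. KIN2 and ICE1 were named after their values were seen. Only ICE1 lay near no region of more replicates, so this count rests mostly on further peaks at genes counted before. The core clock list, with 5 of 28, passed only the second (adjusted permutation p = 0.0997 and 0.042), and the output and heat lists, with 1 gene each, passed neither (adjusted permutation p = 1). Within 100 kb the lowest adjusted p was that of the light regulators, a list with no shared region, at 6 of 23 against 1.09 (adjusted permutation p = 0.00700); no biological explanation by group was tested, as the design has 1 ChIP group.

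Peaks of very high pileup, above 500 reads, formed 5 regions at 2 loci on chromosomes 2 and 3, 4 of them in all 3 replicates, while the highest pileup of any other peak was 157. Their folds were 1.53 to 3.10. Both loci lay within 10 kb of annotated ribosomal RNA genes, and none of 1669 other regions did. Random placement gave 0.0025 such loci on average (one-sided permutation p = 0.0001, the smallest that the placements can give), consistent with reads shared between copies of a repeat, although multiple mapping itself was not measured. Leaving these regions out gave 195 shared regions, and no biological explanation was tested for them.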
